A study of Mus musculus with 8 samples.

How the data were processed

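The data are polyA RNA sequencing libraries from 2 cell fractions, nuclear and cytoplasmic, of mouse liver and of MIN6 cells, a mouse insulinoma line used as a model of pancreatic beta cells. There were 8 libraries, 2 replicates for each fraction of each tissue. Per the labels, MIN6 cells were lysed with a mild detergent and nuclei were spun through a sucrose cushion. Liver nuclear RNA was the soluble part left after chromatin was removed from nuclei, and liver cytoplasmic RNA was what remained in solution after nuclei were collected over sucrose. Fractions were taken from the sample titles. For the 4 MIN6 samples the source field names the opposite fraction to the title, so the values of nuclear long noncoding RNAs in each library were checked against the titles. The labels do not say whether the 2 replicates of a fraction came from separate animals or cultures, nor whether equal replicate numbers mean shared material. The p-values therefore measure spread between these libraries only, which may be technical.

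The deposited values are named FPKM, fragments per kilobase of transcript per 1000000 mapped fragments, 1 per gene and library. Multiplied by transcript length in kb, such values should sum to about 1000000 in each library. In units of 1000000, the sums ran from 0.108 in MIN6 nuclear replicate 2 to 3.55 in liver cytoplasmic replicate 1. The values are thus not scaled to the mapped fragments of each library. Per the labels, the authors aligned reads with TopHat and quantified them with Cuffdiff on mouse build mm10. Versions, the gene annotation, filters and the scaling between libraries are not given in the sources used here. The table held 26520 genes, of which 25522 had an identifier in GENCODE M21, used here for positions, transcript length, exon number, GC content and biotype. Of all genes, 10324 were listed at 0 in every library, and 79 symbols were carried by more than 1 gene. The 13 mitochondrial genes were listed at 0 in every library, so no mitochondrial check of the fractions was possible. An exact 0 is called "listed at 0" and not absence. Read counts are not given. Low FPKM values move in steps of 1 read, so the relative value of 1 read was estimated for each library from the ratios of low values between libraries, counting ratios within 0.004 (log2) of a quotient of small odd numbers. The size of a read came from genes with 1 annotated transcript longer than 1500 bases. These gave an estimated number of reads and a floor, the FPKM of 3 reads on a transcript of 2 kb, which cover counting error only. The estimate was tested on simulated data with known read values for 8 libraries.

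Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend). Each tissue was fitted alone over genes with a mean FPKM of at least 1 in its 4 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Ratios are nuclear over cytoplasmic on the log2 scale, so positive values are higher in the nuclear libraries. Values of named genes are means ± SD of FPKM over 2 libraries (n = 2) unless the 2 libraries are given singly. For a single gene, SE is that of the fit. For a difference or gap of a gene list, SE is taken over the member genes. It then treats genes as independent, and is too small where they vary together. Gene lists with at least 5 tested members were tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01, with adjustment over the lists. The calls were repeated with an estimated correlation, and with fry, which tests whether a list's genes move one way on balance.

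The tests, the thresholds, 26 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists cover nuclear long noncoding RNAs, mRNAs named as nuclear in earlier work, snoRNA host genes, splicing regulators, KRAB zinc fingers, immediate early genes and clock genes. They also cover ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation, mitochondrial mRNAs, proteasome, protein entry to the endoplasmic reticulum, its chaperones, glycolysis, cholesterol synthesis, proliferation, replication histones and a housekeeping panel. Cell identity lists were insulin granule, glucose sensing, beta-cell transcription factors, other islet hormones, exocrine and duct cells, hepatocytes, and stromal, endothelial and immune cells. The list of nuclear mRNAs rests on the study's own topic and may hold genes chosen on these samples, so it is not independent evidence of its direction. The splicing list holds regulators whose transcripts often keep introns or poison exons, so it does not stand for splicing regulators in general. A further 11 lists of liver functions were chosen after the data were seen. The rule took the 10 largest ratios each way among called genes with a mean of at least 10 FPKM in the higher fraction and no overlap between fractions, leaving out unnamed gene models. It also took the 3 highest members of each list and those with the largest and smallest ratio, and a panel of 17 genes. It gave 134 tested genes in MIN6 and 158 in liver. The values of 2 listed genes are not reported here. Which of these stand as examples was decided after their values under other scalings were seen.

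The liver comparison was planned only in case the table held liver libraries. Its alternatives were added after the data were seen. So was the comparison of the ratios between tissues, a limma fit of all 8 libraries after median centring over genes at a mean FPKM of at least 1 in both tissues. The choices varied for MIN6 were a pseudocount of 0.1, no filter, a mean FPKM of at least 10, median centring, rescaling to a sum of 1000000, limma with trend and robust eBayes, the replicate number as a block, an adjusted p under 0.01, and each library left out in turn. Those chosen after seeing the data were leaving out small RNA features (small RNA biotypes or under 200 bases), scaling to the estimated reads, and loess corrections (span 0.3) for GC content or length after centring. Median centring sets the median log2 ratio of each library to the mean of its tissue to 0, so it removes any real difference shared by most genes. The median is taken over genes above 0 in every library fitted. In the comparison between tissues the mean is that of all 8 libraries. Its differences are therefore not exactly those between the centred ratios given for each tissue.

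The fit was tested on simulated data with the spreads of these libraries. With 200 planted genes in MIN6, 8% of planted log2 ratios of 1 were called, 96% of ratios of 2 and 100% of ratios of 3. In liver the shares were 0%, 4% and 66%. With 3008 planted genes in MIN6 they were 71.8%, 99.5% and 99.7%, and with 5176 in liver 19.6%, 80.2% and 97.6%. Unchanged genes were called at 0.14%, 0.08%, 2.05% and 2.22% in these 4 settings, in the same order. The simulated noise was normal and independent between genes. It imitated neither shifts shared by many genes of a library nor values listed at 0, so these rates may not hold for the real libraries. Summaries and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.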

Results

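PolyA RNA of nuclear and cytoplasmic fractions was measured in mouse liver and in MIN6 cells, with 2 libraries for each fraction of each tissue and 8 in all. The series is about mRNA held in the nucleus of mammalian tissues, and each comparison asks which transcripts lay in which fraction. The summed values were 35469 and 35662 FPKM in the MIN6 nuclear libraries and 60421 and 63355 in the cytoplasmic ones. In liver they were 176592 and 104923 FPKM in the nuclear libraries, against 1219625 and 859210 in the cytoplasmic ones. Estimated reads, in units of 1000000, were 3.11 and 2.00 in the MIN6 nuclear libraries, 1.81 and 1.79 in the MIN6 cytoplasmic, 1.97 and 1.75 in the liver nuclear, and 1.48 and 1.41 in the liver cytoplasmic. Relative to MIN6 nuclear replicate 1, 1 read was worth 1.04 times as much in nuclear replicate 2, and 2.25 and 2.35 times in the MIN6 cytoplasmic libraries. It was worth 4.97 and 3.72 times as much in the liver nuclear libraries, and 46.4 and 33.9 times in the liver cytoplasmic ones. The floor of 3 reads on a 2 kb transcript was 0.0776 and 0.0808 FPKM in MIN6 nuclear, 0.174 and 0.183 in MIN6 cytoplasmic, 0.386 and 0.289 in liver nuclear, and 3.603 and 2.63 FPKM in liver cytoplasmic libraries. Ins2 was the highest gene of MIN6 nuclear replicate 1 and of both MIN6 cytoplasmic libraries. The predicted microRNA gene Gm22464, at 2073 FPKM, was the highest in MIN6 nuclear replicate 2. In that library the 10 highest genes held 36.8% of the summed FPKM, against 13.6% in nuclear replicate 1. Counted in estimated reads the order turned, with the 10 highest genes at 8.2% in nuclear replicate 2 and 12.4% in nuclear replicate 1. By FPKM, the small nucleolar RNA Snord104 was highest in both liver nuclear libraries, and Trf and Alb in the liver cytoplasmic ones. The 10 highest genes held 26.9% and 16.3% of the summed FPKM in the liver nuclear libraries. Counted in estimated reads, the 10 highest genes held 7.3% and 6.3%.

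Because title and source field disagree for the MIN6 samples, nuclear noncoding RNAs were compared with the titles. Meg3, an imprinted noncoding RNA, stood at 424 and 97.9 FPKM in the libraries titled nuclear and at 5.28 and 0.990 in those titled cytoplasmic. Neat1, the scaffold RNA of nuclear paraspeckles, stood at 22.5 and 28.6 against 3.05 and 2.68 FPKM. Malat1, an RNA of nuclear speckles, stood at 1.68 and 5.94 against 1.02 and 0.315. The inactive X chromosome RNA Xist was at 0.114 and 0.0203 FPKM in the libraries titled nuclear and listed at 0 in both titled cytoplasmic. These 4 RNAs were thus higher in both libraries titled nuclear than in either titled cytoplasmic. Rian, another noncoding RNA listed as nuclear, did not separate them, at 29.2 and 54.9 against 49.1 and 23.8 FPKM.

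In MIN6 cells, the noncoding RNAs Meg3 and Neat1, 19 of 39 splicing regulators and mRNAs such as Mlxipl and Kif12 were higher in the nuclear libraries, while mRNAs for hormones, secretion, ribosomes and mitochondria were high in the cytoplasmic ones. Meg3 (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726) had the largest nuclear ratio of the named genes, 261 ± 230 against 3.14 ± 3.03 FPKM, a log2 ratio of 5.86 (SE 0.85, adjusted p = 0.00394). Mlxipl, the carbohydrate response transcription factor ChREBP (ENSMUSG00000005373, chromosome 5, 135089890 to 135138382), stood at 163 ± 68.2 against 7.28 ± 2.27 FPKM, a log2 ratio of 4.27 (SE 0.39, adjusted p = 0.00164). In the other direction, the beta-cell hormone Iapp (ENSMUSG00000041681, chromosome 6, 142298423 to 142303961) stood at 67.2 ± 3.24 nuclear and 2029 ± 327 cytoplasmic FPKM, a log2 ratio of −4.89 (SE 0.26, adjusted p = 0.00144). The insulin gene Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) stood at 799 ± 50.8 and 8164 ± 2.58 FPKM, a log2 ratio of −3.35 (SE 0.24, adjusted p = 0.00144).

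Of 6017 genes tested in MIN6, 712 were higher in the nuclear libraries and 2775 in the cytoplasmic ones, so nuclear genes made up 20.4% of the calls. The median log2 ratio of all genes was −0.76. After median centring, 1687 genes were nuclear and 1550 cytoplasmic, a nuclear share of 52.1%, and rescaling to a sum of 1000000 gave 1088 and 1773. All 712 nuclear genes and 1550 of the 2775 cytoplasmic genes were called the same way under the authors' scaling and after centring. A log2 ratio of at least 1 was seen in 776 genes towards the nucleus and of at most −1 in 2607 towards the cytoplasm. Protein-coding genes gave 685 nuclear and 2696 cytoplasmic calls of 5804, long noncoding genes 11 and 21 of 57, and small RNA genes 9 and 2 of 78. After centring, long noncoding genes were 24 nuclear and 12 cytoplasmic. Without MIN6 cytoplasmic replicate 2, limma called 0 genes in either direction (2769 at an unadjusted p under 0.05), and without cytoplasmic replicate 1 it called 64 nuclear and 987 cytoplasmic. Without nuclear replicate 1 the counts were 380 and 2294.

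**Figure D1:**
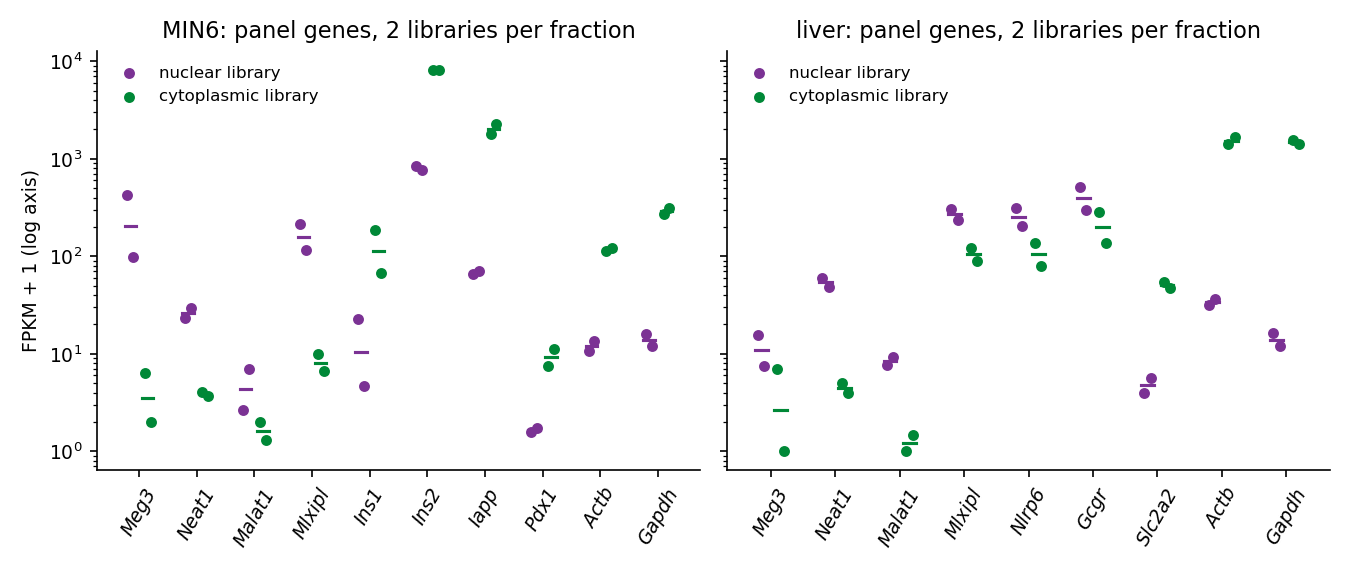
FPKM + 1 (log axis) of panel genes in each library of MIN6 (left) and liver (right). Points are single libraries, purple nuclear and green cytoplasmic, and bars are means on the log scale of 2 libraries; Meg3 and Mlxipl in MIN6 lie far higher in the nuclear libraries (log2 ratios 5.86 and 4.27), Iapp and Gapdh in the cytoplasmic ones (−4.89 and −4.40).

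The other large nuclear ratios in MIN6 belonged to mRNAs of several kinds. Kif12, a kinesin motor protein, stood at 111 ± 77.6 against 2.05 ± 0.732 FPKM, a log2 ratio of 5.02 (SE 0.55, adjusted p = 0.00208). Rgs11, a regulator of G protein signalling, stood at 45.6 ± 34.4 against 0.340 ± 0.480 FPKM, a log2 ratio of 4.94, with 1 cytoplasmic library listed at 0. Zfp692, a zinc finger gene, stood at 36.4 ± 23.8 against 0.670 ± 0.490 FPKM, a log2 ratio of 4.36. Lmtk3, Pcyt2 (an enzyme of phosphatidylethanolamine synthesis), Crocc (a ciliary rootlet protein), Abca7 (a lipid transporter) and Col27a1 (a collagen) had log2 ratios of 4.66, 4.12, 4.09, 4.01 and 3.98. On the cytoplasmic side stood H3f3a, a replication-independent histone H3 gene, at 2.29 ± 0.479 and 109 ± 12.2 FPKM, a log2 ratio of −5.06. Of its exon bases, 22.8% are shared with other annotated genes. The neuropeptide gene Npy stood at 12.7 ± 1.08 and 397 ± 80.3 FPKM, a log2 ratio of −4.84. Gapdh, the glycolytic enzyme, stood at 12.97 ± 2.93 and 292 ± 29.5 FPKM, a log2 ratio of −4.40 (SE 0.28, adjusted p = 0.00144). Gng12 (a G protein subunit), Scg2 (secretogranin 2), Ppia (cyclophilin A), Spp1 (osteopontin), Rab7 (a late endosome GTPase) and Cck (cholecystokinin) had log2 ratios of −5.02, −4.54, −4.51, −4.43, −4.37 and −4.36. After centring these genes kept their direction, with Meg3 at 6.80, Mlxipl at 5.36, Iapp at −3.71 and Gapdh at −3.26.

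Among the lists, 4 lay towards the nucleus in MIN6 relative to other genes. Splicing regulators, which shape exon choice, had 39 tested members, of which 19 were nuclear, 5 cytoplasmic and 15 not past the threshold, and adjusted over the list alone 19 and 5. Their mean log2 ratio lay 1.50 above that of other genes (camera, adjusted p = 1.42e-08, and adjusted p = 0.320 with an estimated correlation). Srrm2, a large spliceosome scaffold protein, stood at 39.9 ± 21.6 against 2.05 ± 0.908 FPKM, a log2 ratio of 3.67 (SE 0.46, adjusted p = 0.00285). Snrnp70, a protein of the U1 particle, stood at 73.7 ± 5.67 against 11.1 ± 1.67 FPKM, a log2 ratio of 2.63 (SE 0.25, adjusted p = 0.00171). Srsf1, a splicing factor, lay the other way at −1.77 (SE 0.43, adjusted p = 0.0187), a call lost after centring (−0.76). The list of nuclear long noncoding RNAs had 5 tested members, 3 nuclear and 0 cytoplasmic, and adjusted over the list alone 4 and 0. It lay 3.32 above other genes (adjusted p = 0.000762, and adjusted p = 0.320 with an estimated correlation). Neat1 had a log2 ratio of 2.77 (SE 0.26, adjusted p = 0.00169), while Malat1 at 1.40 (SE 0.52, adjusted p = 0.0634) and Rian at 0.22 (adjusted p = 0.704) did not pass.

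The mRNAs listed as nuclear from earlier work had 6 tested members, 5 nuclear and 1 cytoplasmic, and adjusted over the list alone 5 and 1. The list lay 2.70 above other genes (adjusted p = 0.000229, and adjusted p = 0.320 with an estimated correlation). Besides Mlxipl it held Clk4, a kinase of splicing factors, at 24.1 ± 9.51 against 3.66 ± 0.359 FPKM, a log2 ratio of 2.38 (adjusted p = 0.00386). Its cytoplasmic member was Ddx5, an RNA helicase, at −1.16 (SE 0.30, adjusted p = 0.0207), which stood at −0.02 after centring and at 0.28 with a GC correction as well. The nuclear mRNA and splicing lists share 4 genes. Host genes of small nucleolar RNAs had 6 tested members, 3 nuclear and 0 cytoplasmic, and adjusted over the list alone 3 and 0. They lay 1.69 above other genes (adjusted p = 0.00264, and adjusted p = 0.321 with an estimated correlation). Of these, 2810008D09Rik had a log2 ratio of 1.86 (adjusted p = 0.00722), and Gas5, at 0.85 (adjusted p = 0.124), did not pass. After centring, 27 splicing regulators, 4 nuclear long noncoding RNAs, 5 mRNAs of the nuclear list and 5 host genes were nuclear, and 0 of each were cytoplasmic.

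The secretory machinery of MIN6 lay towards the cytoplasm. Insulin granule genes had 22 tested members, 1 nuclear and 19 cytoplasmic, and adjusted over the list alone 1 and 19. They lay at −1.49 relative to other genes (adjusted p = 0.00265, and adjusted p = 0.320 with an estimated correlation). Ins1, the other mouse insulin gene, stood at 12.8 ± 12.8 against 126 ± 85.0 FPKM, a log2 ratio of −3.44 (SE 0.86, adjusted p = 0.0196), and the granule protein gene Chga was at −1.38 (adjusted p = 0.0154) and at −0.20 after centring, where it did not pass. The nuclear member was Ptprn, a granule membrane protein, at 70.4 ± 25.3 against 24.8 ± 2.66 FPKM, a log2 ratio of 1.43 (SE 0.33, adjusted p = 0.0155). Of 25 tested genes for protein entry into the endoplasmic reticulum, 25 were cytoplasmic and 0 nuclear, with 25 adjusted over the list alone, and they lay at −1.71 relative to other genes (adjusted p = 6.86e-06, and adjusted p = 0.320 with an estimated correlation). The translocon subunits Sec61b and Sec61g had log2 ratios of −3.43 and −3.35. Of 31 tested chaperone and stress response genes of that compartment, 25 were cytoplasmic and 0 nuclear, with 26 adjusted over the list alone, and they lay at −1.16 (adjusted p = 0.000963, and adjusted p = 0.321 with an estimated correlation). The list shares 8 genes with the previous one. The disulphide isomerase P4hb, the chaperone Hsp90b1 and the growth factor Manf had log2 ratios of −2.65, −2.41 and −3.48. After centring, insulin granule genes were 12 cytoplasmic and 2 nuclear, entry genes 20 and 0, and chaperones 16 and 3.

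Genes for ribosomal proteins, oxidative phosphorylation, translation factors and the proteasome, and the housekeeping panel, also lay towards the cytoplasm in MIN6. Of 68 tested ribosomal protein genes, 62 were cytoplasmic and 0 nuclear, with 63 adjusted over the list alone, at −1.77 relative to other genes (adjusted p = 6.78e-07, and adjusted p = 0.565 with an estimated correlation). Rps9 stood at 17.7 ± 7.30 and 192 ± 18.4 FPKM, a log2 ratio of −3.42 (SE 0.35, adjusted p = 0.00182), and Rpl10 had a log2 ratio of −3.69. Of 46 tested nuclear-encoded genes of oxidative phosphorylation, 41 were cytoplasmic and 0 nuclear, with 43 adjusted over the list alone, at −1.61 (adjusted p = 6.78e-07, and adjusted p = 0.472 with an estimated correlation). The cytochrome oxidase subunit genes Cox6b1 and Cox4i1 had log2 ratios of −3.92 and −2.68. Of 32 translation factor genes, 20 were cytoplasmic and 0 nuclear, with 20 adjusted over the list alone, at −0.82 (adjusted p = 0.00657, and adjusted p = 0.551 with an estimated correlation). Eef1a1 stood at 41.6 ± 7.95 and 572 ± 36.1 FPKM, a log2 ratio of −3.76, and Eif5a had −3.62. Of 31 proteasome genes, 21 were cytoplasmic and 0 nuclear, with 22 adjusted over the list alone, at −0.97 (adjusted p = 0.00264, and adjusted p = 0.551 with an estimated correlation). The subunits Psmb7 and Psmd13 had log2 ratios of −3.17 and −2.50. The housekeeping panel had 12 cytoplasmic and 0 nuclear of 15, with 12 adjusted over the list alone, at −1.50 (adjusted p = 0.00519, and adjusted p = 0.320 with an estimated correlation), and Actb, cytoplasmic actin, stood at −3.29 (SE 0.26, adjusted p = 0.00148). After centring, the cytoplasmic and nuclear genes were 41 and 1 of ribosomal proteins, 34 and 1 of oxidative phosphorylation, 10 and 1 of translation factors, 14 and 0 of the proteasome, and 8 and 1 of the housekeeping panel. The nuclear replicates differed in these groups: replicate 1 lay above replicate 2 by a median of 1.03 (log2) in ribosomal protein genes, 0.57 in translation factors, 0.52 in proteasome genes and 0.42 in oxidative phosphorylation, against 0.18 over all genes, while the cytoplasmic replicates differed by 0.02 in ribosomal protein genes. Expression level limits these list tests and those of the secretory lists. The median log2 ratio was −0.76 over all genes tested, but −1.75 over genes at a mean FPKM of at least 10. Translation factors and proteasome genes had list medians of −1.28 and −1.75, not below the latter. Ribosomal protein, oxidative phosphorylation and housekeeping genes had list medians of −2.40, −2.35 and −2.33.

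Other MIN6 lists did not pass the test against other genes. Glucose sensing genes were split, 5 nuclear and 5 cytoplasmic of 11 (adjusted p = 0.201). Abcc8, a subunit of the ATP-sensitive potassium channel, stood at 201 ± 91.1 against 36.0 ± 3.48 FPKM, a log2 ratio of 2.37 (SE 0.38, adjusted p = 0.00516). G6pc2, an islet glucose-6-phosphatase, and the uncoupling protein gene Ucp2 lay the other way at −2.60 (SE 0.32, adjusted p = 0.00269) and −3.74 (adjusted p = 0.00144). Beta-cell transcription factors had 1 nuclear and 7 cytoplasmic members of 13 (adjusted p = 0.528). Pdx1 stood at 0.670 ± 0.119 and 8.43 ± 2.67 FPKM, a log2 ratio of −2.47 (SE 0.30, adjusted p = 0.00264), and Rfx6 at 0.97 (SE 0.28, adjusted p = 0.0306). Glycolysis had 1 nuclear and 8 cytoplasmic of 14 (adjusted p = 0.245), with Aldoa at −2.22, cholesterol synthesis 0 and 11 of 19 (adjusted p = 0.126), with Idi1 at −2.35 and Dhcr7 at −2.08, and proliferation 0 and 17 of 30 (adjusted p = 0.232), with Cdk1 at −2.59. Clock genes had 1 and 1 of 9 (adjusted p = 0.245), with Per2 at 1.12, immediate early genes 0 and 4 of 13 (adjusted p = 0.245), with Mcl1 at −1.43, and KRAB zinc fingers 1 and 2 of 7 (adjusted p = 0.603), with Zfp688 at 0.88. The calls of these 8 lists were as many when adjusted over the list alone. After centring, immediate early genes turned to 6 nuclear and 0 cytoplasmic, clock genes were 4 and 1, glucose sensing 6 and 3, and KRAB zinc fingers 1 and 0. Beta-cell transcription factors were then 3 nuclear and 4 cytoplasmic, glycolysis 4 and 7, cholesterol synthesis 1 and 4, and proliferation 5 and 6. The clock and KRAB lists had medians of −0.07 and −0.33 but lay above other genes in the test, and the immediate early list had a median of 0.06 and a mean of −0.24. Glucose sensing had a median just below 0 and a mean of 0.01. The cholesterol list passed without MIN6 nuclear replicate 1 (at −0.52, adjusted p = 0.0475).

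Lists with fewer than 5 tested members in MIN6 have no list test. All 3 tested genes of other islet hormones were cytoplasmic, Gcg (glucagon) at −3.53, Sst (somatostatin) at −2.98 (SE 0.55, adjusted p = 0.00752) and Ttr (transthyretin) at −2.68. All 3 tested exocrine and duct genes were cytoplasmic too, among them the duct keratins Krt7 and Krt19 at −1.74 and −1.27, and so were the 3 tested replication histones, among them Hist1h1c at −1.57. Replication histones are listed as genes whose messengers lack a poly(A) tail, and these are polyA libraries. Of 34 such genes in the table, 23 were listed at 0 in all MIN6 libraries, so the 3 do not stand for the list. After centring 1 of the exocrine and duct genes, Spp1, was cytoplasmic, while Krt7 and Krt19 (−0.74 and −0.67) did not pass, and all 3 islet genes and all 3 histones still were. Of 2 hepatocyte genes tested, 1 was cytoplasmic, and Cyp2e1 did not pass (0.89, adjusted p = 0.161) but was nuclear after centring. No stromal, endothelial or immune marker was tested.

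In liver, mRNAs for hepatocyte markers, ribosomes and mitochondria were far higher in the cytoplasmic libraries, while Neat1 was higher in the nuclear ones and splicing regulators lay towards the nucleus relative to other genes (adjusted p = 1.19e-17, and adjusted p = 0.534 with an estimated correlation). Neat1 (ENSMUSG00000092274, chromosome 19, 5824708 to 5845478) stood at 53.5 ± 7.85 against 3.52 ± 0.777 FPKM, a log2 ratio of 3.595 (SE 0.44, adjusted p = 0.00422). Rsrp1, an arginine and serine rich protein gene (ENSMUSG00000037266, chromosome 4, 134923592 to 134927671), stood at 349 ± 95.5 against 49.0 ± 0.907 FPKM, a log2 ratio of 2.78 (SE 0.45, adjusted p = 0.00715). Albumin (Alb, ENSMUSG00000029368, chromosome 5, 90460897 to 90476602) stood at 693 ± 62.8 nuclear and 37230 ± 6169 cytoplasmic FPKM, a log2 ratio of −5.74 (SE 0.43, adjusted p = 0.00346). Scd1, the stearoyl-CoA desaturase gene, stood at 2.21 ± 0.129 and 418 ± 120.0 FPKM, a log2 ratio of −6.998 (SE 0.45, adjusted p = 0.00346).

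Of 10353 genes tested in liver, 303 were nuclear and 5197 cytoplasmic, a nuclear share of 5.5%, with a median log2 ratio of −1.64 over all genes. After centring, 1473 were nuclear and 1181 cytoplasmic, a nuclear share of 55.5%. Rescaling to a sum of 1000000 gave 1513 and 534 (73.9% nuclear, median 0.54), and scaling to the estimated reads, an alternative chosen after seeing the data, gave 2100 and 913 (69.7% nuclear). The side on which most liver genes fell thus turned with the scaling. All 303 nuclear genes and 1181 of the 5197 cytoplasmic ones were called the same way under the authors' scaling and after centring. Of the 303 nuclear genes, 225 were listed at 0 in both cytoplasmic libraries, so their ratios depend on the pseudocount, and after centring this held for 234 of 1473. Of the 712 nuclear genes of MIN6, 26 were listed at 0 in both cytoplasmic libraries. A log2 ratio of at least 1 was seen in 647 genes and of at most −1 in 7043. Protein-coding genes gave 252 nuclear and 5063 cytoplasmic calls of 9943, long noncoding genes 17 and 47 of 166, and small RNA genes 24 and 2 of 82. After centring, long noncoding genes were 39 nuclear and 7 cytoplasmic. Without liver nuclear replicate 1, limma called 0 genes in either direction (4275 at an unadjusted p under 0.05), and without nuclear replicate 2 also 0 (3691).

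**Figure D2:**
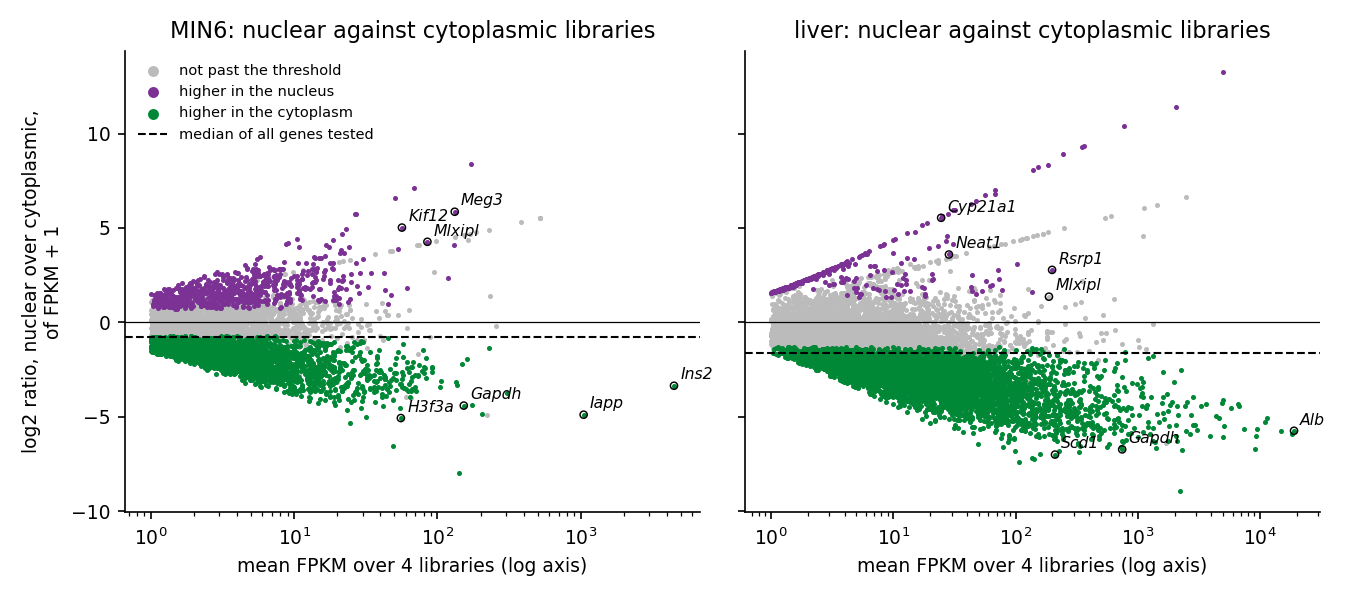
Log2 ratio of nuclear over cytoplasmic FPKM + 1 against the mean FPKM of 4 libraries (log axis) for each gene tested in MIN6 (left) and liver (right). Purple and green points passed the threshold under the authors' scaling and the dashed line is the median of all genes, −0.76 in MIN6 and −1.64 in liver; centring moves this line close to 0, and the purple points on the upper straight edge in liver are genes listed at 0 in both cytoplasmic libraries, as 225 of 303 nuclear genes were.

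Many of the named liver mRNAs with large nuclear values were listed at 0 in both cytoplasmic libraries, where 3 reads on a 2 kb transcript would be worth 3.603 and 2.63 FPKM. Cyp21a1, a steroid hydroxylase gene, stood at 68.4 and 30.1 FPKM in the nuclear libraries, Cyp2j9, another cytochrome P450, at 44.8 and 15.7, and Gramd1a, a cholesterol transporter, at 28.6 and 22.8. Sap25, Acrbp and Ramp2 stood at 19.5 and 21.7, 15.8 and 15.3, and 12.1 and 11.5 FPKM. Of the exon bases of these 3 genes, 76.5%, 32.5% and 33.4% are shared with other annotated genes. Fam193b stood at 70.6 and 43.1 against 0 and 8.93 FPKM, a log2 ratio of 4.16 (SE 1.13, adjusted p = 0.0290). Tnxb, a matrix protein gene, stood at 61.4 and 26.8 against 5.39 and 0, Cabyr at 48.3 and 25.9 against 4.67 and 0, and the adrenergic receptor gene Adrb3 at 23.3 and 15.4 against 0 and 1.43 FPKM.

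Large cytoplasmic ratios in liver belonged to genes of several kinds. Hspb1, a small heat shock protein, stood at 0.891 ± 0.182 and 270 ± 14.1 FPKM, a log2 ratio of −7.16 (SE 0.42, adjusted p = 0.00346). Nme2, a nucleoside diphosphate kinase, stood at 0.225 ± 0.142 and 283 ± 304 FPKM, a log2 ratio of −7.24 (SE 0.98, adjusted p = 0.00504), and 48.9% of its exon bases are shared with other genes. Gapdh stood at 13.1 ± 2.99 and 1477 ± 102 FPKM, a log2 ratio of −6.72, and the protease inhibitor gene Serpina1a at 172 ± 6.64 and 18170 ± 2522 FPKM, a log2 ratio of −6.71. The ribosomal gene Rpl5, Rgn (regucalcin), the phosphoglycerate kinase copy Pgk1-rs7, the glutathione transferase Gstm1 and the peroxiredoxin Prdx1 had log2 ratios of −6.85, −6.81, −6.80, −6.74 and −6.66. After centring Scd1 stood at −4.81 and Gapdh at −4.32.

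The mRNAs listed as nuclear from earlier work had 10 tested members in liver, 2 nuclear, 2 cytoplasmic and 6 not past the threshold, and adjusted over the list alone 2 and 2. After centring 8 were nuclear and 0 cytoplasmic. The list lay 2.12 above other genes (adjusted p = 9.48e-06, and adjusted p = 0.534 with an estimated correlation). Mlxipl stood at 270 ± 51.1 against 105 ± 23.1 FPKM, a log2 ratio of 1.36 (SE 0.45, adjusted p = 0.0523), which did not pass. Nlrp6, an inflammasome receptor gene (chromosome 7, 140920902 to 140929192), stood at 259 ± 78.1 against 107 ± 41.1 FPKM, a log2 ratio of 1.28 (SE 0.52, adjusted p = 0.0882). The glucagon receptor gene Gcgr (chromosome 11, 120530699 to 120538986) stood at 405 ± 148 against 211 ± 105 FPKM, a log2 ratio of 0.98 (SE 0.58, adjusted p = 0.205). Mlxipl, Nlrp6 and Gcgr passed after centring, at 3.81, 3.73 and 3.43. Clk1, a kinase of splicing factors, passed under both, at 94.97 ± 35.3 against 20.4 ± 8.45 FPKM, a log2 ratio of 2.17 (SE 0.54, adjusted p = 0.0229). Ddx5 stood at 151 ± 8.37 and 153 ± 45.4 FPKM, a log2 ratio of 0.01 (adjusted p = 0.988).

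Of 41 splicing regulators tested in liver, 8 were nuclear and 1 cytoplasmic, with 3 and 1 adjusted over the list alone and 37 and 0 after centring. They lay 2.25 above other genes (adjusted p = 1.19e-17, and adjusted p = 0.534 with an estimated correlation), with Rsrp1 and Clk1 among the nuclear members. Nuclear long noncoding RNAs had 5 tested members, 2 nuclear and 1 cytoplasmic, with 2 and 1 adjusted over the list alone and 3 and 0 after centring. They lay 2.81 above other genes (adjusted p = 0.000275, and adjusted p = 0.534 with an estimated correlation). Malat1 stood at 6.76 and 8.38 against 0 and 0.477 FPKM, a log2 ratio of 2.81 (SE 0.46, adjusted p = 0.00728), and Meg3 at 14.5 and 6.56 against 6.03 and 0 FPKM (adjusted p = 0.147). Host genes of small nucleolar RNAs were 2 nuclear and 0 cytoplasmic of 10, with 2 and 0 adjusted over the list alone and 6 and 0 after centring, and lay 2.78 above other genes (adjusted p = 1.15e-06, and adjusted p = 0.534 with an estimated correlation). Of these, 2810008D09Rik stood at 61.7 and 44.6 against 0 and 4.17 FPKM.

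Immediate early genes and KRAB zinc fingers lay above other genes in liver although their medians, −0.94 and −0.89, were negative. Both lists are low in liver, with a median mean FPKM of 1.64 and 0.60 over all listed members, tested or not. The floor was 3.603 and 2.63 FPKM in the cytoplasmic libraries. The pseudocount draws ratios of low genes towards 0, above the median of −1.64 over all genes, so part of this result may come from low values. Of 25 immediate early genes 7 were cytoplasmic and 0 nuclear, with 7 adjusted over the list alone, which turned to 5 nuclear and 0 cytoplasmic after centring, at 0.97 above other genes (adjusted p = 0.0474, and adjusted p = 0.534 with an estimated correlation). Gadd45g, a growth arrest gene, stood at 39.1 ± 17.8 against 19.4 ± 4.28 FPKM, a log2 ratio of 0.91 (adjusted p = 0.194). Of 53 KRAB zinc fingers 11 were cytoplasmic and 0 nuclear, with 0 adjusted over the list alone, which turned to 12 nuclear and 0 cytoplasmic after centring, at 0.86 above other genes (adjusted p = 0.0284, and adjusted p = 0.697 with an estimated correlation), and Zfp655 was at −2.46 (adjusted p = 0.0111). The call of immediate early genes was lost without liver cytoplasmic replicate 1 (adjusted p = 0.320), nuclear replicate 1 (0.0640) or nuclear replicate 2 (0.174), and that of KRAB zinc fingers without cytoplasmic replicate 2 (0.441) or nuclear replicate 1 (0.0640).

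Hepatocyte genes lay towards the cytoplasm in liver, 19 cytoplasmic and 0 nuclear of 20, with 19 adjusted over the list alone, at −2.80 relative to other genes (adjusted p = 1.07e-05, and adjusted p = 0.534 with an estimated correlation). After centring 18 were cytoplasmic and 1 nuclear. The iron carrier Trf (63.5% of exon bases shared with other genes) stood at 594 ± 75.6 and 36190 ± 10620 FPKM, a log2 ratio of −5.90. The nuclear gene after centring was G6pc, the hepatic glucose-6-phosphatase, at 250 ± 69.7 and 420 ± 150 FPKM, a log2 ratio of −0.72 (SE 0.51, adjusted p = 0.274) that became 1.74. Of 69 ribosomal protein genes 68 were cytoplasmic and 0 nuclear, with 68 adjusted over the list alone, at −3.21 (adjusted p = 8.49e-14, and adjusted p = 0.534 with an estimated correlation). Of 46 oxidative phosphorylation genes 46 were cytoplasmic, with 46 adjusted over the list alone, at −2.94 (adjusted p = 1.89e-10, and adjusted p = 0.534 with an estimated correlation). Cox6b1 stood at 11.9 ± 0.0216 and 951 ± 214 FPKM, a log2 ratio of −6.19 (SE 0.44, adjusted p = 0.00346). Of 34 translation factors 31 were cytoplasmic and 0 nuclear, with 31 adjusted over the list alone, at −1.66 (adjusted p = 0.000118, and adjusted p = 0.560 with an estimated correlation), and Eef1a1 was at −6.08. After centring 60 ribosomal protein genes, 38 of oxidative phosphorylation and 13 translation factors were cytoplasmic, and 0 were nuclear. The haemoglobin gene Hbb-bs, a red blood cell transcript chosen after its values were seen, stood at 10.8 and 1.55 nuclear against 1102 and 243 cytoplasmic FPKM. Mature red blood cells have no nucleus, so its direction does not bear on mRNA held in the nucleus.

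The remaining liver lists towards the cytoplasm were the proteasome (31 cytoplasmic of 31, with 31 adjusted over the list alone, at −1.93, adjusted p = 1.59e-05), with Psmb7 at −5.26, and protein entry into the endoplasmic reticulum (27 of 27, with 27 adjusted over the list alone, at −1.86, adjusted p = 1.87e-05), with Sec61b at −5.33. Chaperones of that compartment had 30 of 35 (30 adjusted over the list alone, at −1.19, adjusted p = 0.000255), with P4hb at −4.39, and the housekeeping panel 14 of 15 (14 adjusted over the list alone, at −2.38, adjusted p = 0.000322), with Actb at −5.51. Cholesterol synthesis had 19 of 22 (20 adjusted over the list alone, at −1.43, adjusted p = 0.00299), with Fdps at −5.30 and Ebp at −4.30. Glycolysis had 11 of 14 (11 adjusted over the list alone, at −1.84, adjusted p = 0.0220), with Tpi1 at −5.49 and Ldha at −4.86, a list call lost without liver cytoplasmic replicate 2 (adjusted p = 0.326). Under the authors' scaling 0 genes of these 6 lists were nuclear, and each list had adjusted p = 0.534 with an estimated correlation. After centring, 12 proteasome genes, 7 entry genes, 8 of the housekeeping panel, 7 of cholesterol synthesis and 7 of glycolysis were cytoplasmic and 0 nuclear, while chaperones were 7 cytoplasmic and 2 nuclear. Expression level limits these tests too. The median log2 ratio was −1.64 over all liver genes tested, but −2.69 at a mean FPKM of at least 10. The medians of these 6 lists ran from −4.07 (housekeeping panel) to −3.01 (chaperones).

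Liver lists that did not pass were glucose sensing, beta-cell transcription factors, clock genes, proliferation, and stromal, endothelial and immune markers. Of 9 glucose sensing genes 5 were cytoplasmic and 0 nuclear, with 5 and 1 adjusted over the list alone (adjusted p = 0.949). The glucose transporter gene Slc2a2 stood at 3.82 ± 1.19 and 49.7 ± 4.89 FPKM, a log2 ratio of −3.41 (SE 0.45, adjusted p = 0.00474), and Ucp2 at −5.41. The mean of this list lay at −0.39 relative to other genes although the test placed it above them. Beta-cell transcription factors had 3 cytoplasmic of 8 (2 adjusted over the list alone, adjusted p = 0.916), clock genes 8 of 17 (8 adjusted over the list alone, adjusted p = 0.949) and proliferation 7 of 23 (4 adjusted over the list alone, adjusted p = 0.457), each with 0 nuclear genes under the authors' scaling. The transcription factor Hnf4a was at −3.24 and the replication gene Mcm6 at −3.19. The means of the first 2 lay 0.18 and 0.32 above other genes although the test placed them below. The proliferation list passed without liver cytoplasmic replicate 2 (0.75 above other genes, adjusted p = 0.0259). Stromal, endothelial and immune markers had 1 nuclear and 8 cytoplasmic of 15 (1 and 9 adjusted over the list alone, adjusted p = 0.886). The medians of this list and of proliferation were −1.48 and −1.05 although the test placed both above other genes. After centring, few members passed either way: glucose sensing had 2 nuclear and 1 cytoplasmic, beta-cell transcription factors 1 and 0, clock genes 2 and 0, proliferation 1 and 2, and the stromal, endothelial and immune markers 1 and 0. The direction of the list test then turned in the first 4 of these, which still did not pass. The nuclear marker under the authors' scaling was Ptprc, the leukocyte marker CD45, at 6.17 and 6.92 against 1.97 and 0 FPKM. Without a list test, 3 of 4 exocrine and duct genes were cytoplasmic, with Amy1 at −4.34 (32.7% of exon bases shared), 4 of 4 replication histones, with Hist1h2bc at −4.41, 2 of 2 other islet genes, with Ttr at −4.53, and 1 of 4 insulin granule genes, Ero1lb. After centring 1 gene of each of these 4 lists was cytoplasmic (Amy1, Hist1h2bc, Ttr and Ero1lb), and 1 granule gene, Vamp2, was nuclear. Of 34 replication histone genes in the table, 25 were listed at 0 in all liver libraries, so the 4 tested do not stand for that list. Ins1, Ins2, Iapp, Pdx1 and Xist were listed at 0 in all liver libraries.

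**Figure D3:**
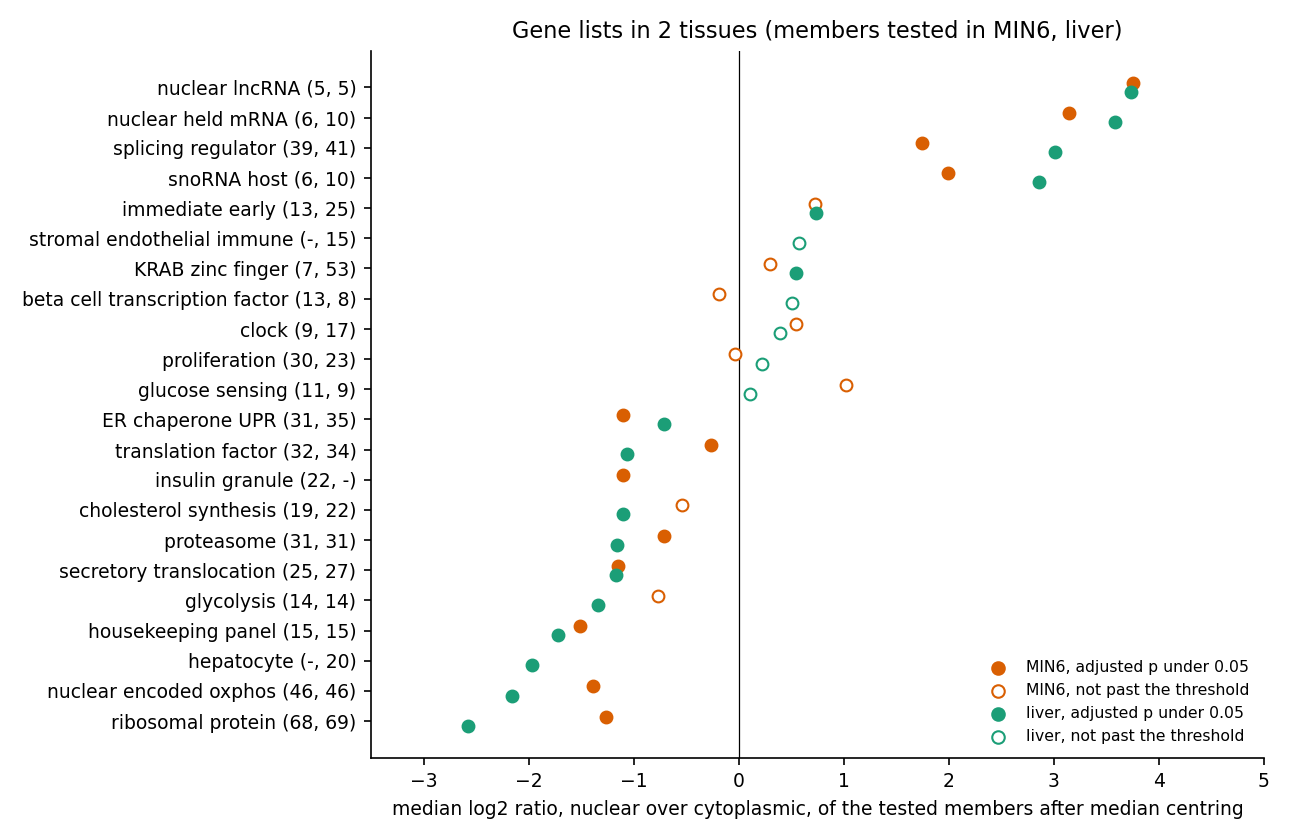
Median log2 ratio, nuclear over cytoplasmic, of the tested members of each gene list after median centring, in MIN6 (orange) and liver (green), with the members tested in brackets. Filled points passed camera at a preset correlation, among them splicing regulators (37 nuclear members of 41 in liver) and ribosomal protein genes (60 cytoplasmic of 69); under the authors' scaling no list passed with an estimated correlation.

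Across the 5315 genes tested in both tissues, the ratios of MIN6 and liver were related, with a Spearman rho of 0.73 and a Pearson r of 0.73 under the authors' scaling, and 0.74 and 0.74 after centring. Genes are not independent replicates, so these correlations have no p, and the Fisher tests of overlap treat genes as independent. After GC content, length and both expression levels were removed, the rank correlation was 0.69. Under the authors' scaling 89 genes were nuclear in both tissues, of 609 in MIN6 and 142 in liver, where 16.3 would be expected for independent lists (odds ratio 15.0, Fisher's exact test, p = 6.77e-50). Genes cytoplasmic in both numbered 2064, of 2492 and 2998, against 1405.6 expected (odds ratio 9.75, Fisher's exact test, p = 1.88e-308). After centring the shared nuclear genes were 639 (235.4 expected, odds ratio 13.3) and the shared cytoplasmic genes 574 (209.3 expected, odds ratio 11.8). Neat1, Snrnp70, Clk1, Clk4, Rsrp1, Zfp692, Crocc and Col27a1 were among the 89. Opposite calls were fewer, 39 genes nuclear in MIN6 and cytoplasmic in liver, and 5 the other way, which became 6 and 5 after centring.

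**Figure D4:**
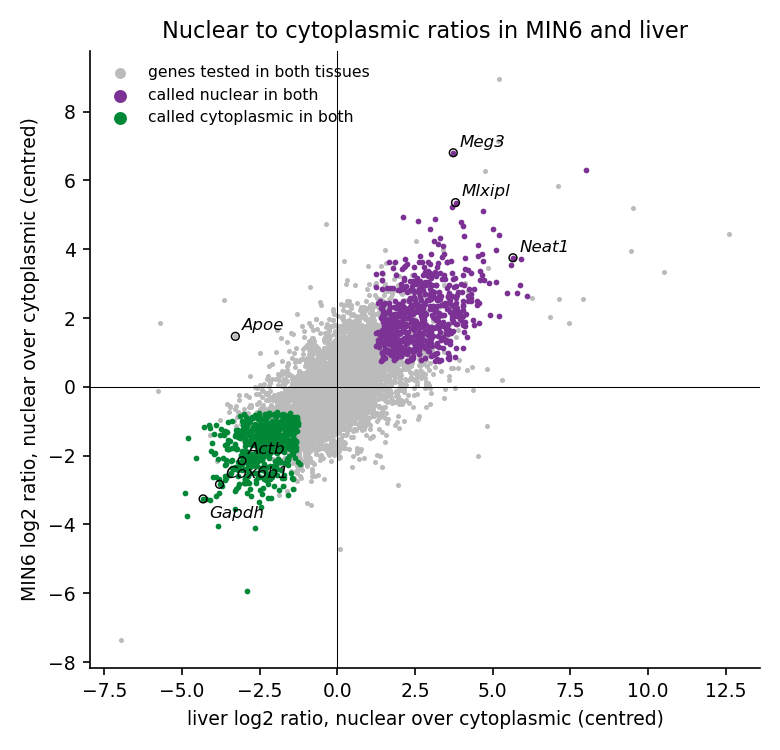
Log2 ratio of nuclear over cytoplasmic libraries after median centring in liver (horizontal) and MIN6 (vertical) for 5315 genes tested in both. Purple points were called nuclear in both (639 genes) and green points cytoplasmic in both (574), with Neat1 and Mlxipl at the nuclear end and Gapdh at the cytoplasmic end.

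Across genes, the log2 ratio was also compared with 4 gene properties in each tissue, 8 relations in all, the GC relation being added after the data were seen. In MIN6 Spearman's rho was −0.18 with expression level (SD between replicates 0.19), 0.22 with transcript length (0.05), 0.24 with exon number and 0.29 with GC content (0.06). The relation with expression level was no larger than its spread, and it stood at 0.02 without MIN6 cytoplasmic replicate 2. In liver rho was −0.57 with expression level, 0.20 with length, 0.12 with exon number and 0.09 with GC content. The level and the ratio came from the same libraries, and in liver the cytoplasmic values were far larger than the nuclear ones. The pseudocount also draws the ratios of low genes towards 0. The negative relation with level in liver may therefore be built in to a large part. Annotation paired with 99.5% and 99.3% of the genes tested.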

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

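All tests in this part were chosen after the data were seen. Each result here was taken up because the nuclear to cytoplasmic ratio differed between MIN6 and liver in a test of that difference over the 5315 genes tested in both tissues, after median centring.

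In that test 63 genes were more nuclear in MIN6 and 47 more nuclear in liver (limma, 1385 at an unadjusted p under 0.05). Without 1 library the counts were 0 and 0 (MIN6 cytoplasmic replicate 1), 0 and 1 (MIN6 cytoplasmic replicate 2), 1 and 3 (MIN6 nuclear replicate 1), 233 and 144 (MIN6 nuclear replicate 2), 7 and 9 (liver cytoplasmic replicate 1), 30 and 33 (liver cytoplasmic replicate 2), 0 and 0 (liver nuclear replicate 1), and 3 and 0 (liver nuclear replicate 2). The 2 settings with 0 and 0 had 969 and 1127 genes at an unadjusted p under 0.05. Meg3 did not pass (4.17, SE 1.00, adjusted p = 0.0576), nor did Mlxipl (1.78, adjusted p = 0.0805) or Neat1 (−1.06, adjusted p = 0.179). Glucose sensing genes, 5 in this test, lay 1.67 further towards the nucleus in MIN6 relative to other genes (adjusted p = 0.0133). The call was lost without MIN6 nuclear replicate 2 and under the authors' scaling (adjusted p = 0.0507). With 1 library left out the difference ranged from 1.49 to 1.86. Glycolysis genes lay 0.87 further towards the nucleus in MIN6 (adjusted p = 0.0133), a call lost under the authors' scaling (adjusted p = 0.0577) and at a mean FPKM of at least 10 in both tissues (0.0821). Oxidative phosphorylation genes lay 0.73 further (adjusted p = 0.000365), a call lost at that mean FPKM (adjusted p = 0.0549). The calls of these last 2 lists were kept without each library in turn. Proteasome genes lay 0.49 further towards the nucleus in MIN6 (adjusted p = 0.0279), a call lost without MIN6 nuclear replicate 1 (adjusted p = 0.108) or liver nuclear replicate 2 (0.0704) and at a mean FPKM of at least 10 in both tissues (0.396). Translation factors lay 0.51 further towards the nucleus in MIN6 (adjusted p = 0.0346), a call lost without MIN6 nuclear replicate 1 (adjusted p = 0.0735), liver cytoplasmic replicate 1 (0.116) or liver nuclear replicate 2 (0.106) and at that mean FPKM (0.246). Splicing regulators differed by −0.69, further towards the nucleus in liver (adjusted p = 0.00303), and this was −0.44 with a GC correction (adjusted p = 0.0427) and ranged from −0.89 to −0.48 when 1 library was left out, the smallest without MIN6 nuclear replicate 1. Under the authors' scaling the differences were 1.16 for oxidative phosphorylation, 0.79 for the proteasome and 0.77 for translation factors, and at a mean FPKM of at least 10 in both tissues 0.27 for the proteasome. None of these list calls held with an estimated correlation (adjusted p = 0.522 for each, the highest over the alternatives), and the lowest adjusted p was 0.00623 for glucose sensing, 0.00636 for glycolysis, 3.72e-07 for oxidative phosphorylation, 0.00215 for the proteasome, 0.00733 for translation factors and 0.000250 for splicing regulators.

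Ribosomal protein genes lay further towards the cytoplasm in liver, by 1.11 (log2) relative to other genes (adjusted p = 1.75e-09, and adjusted p = 0.522 with an estimated correlation), with 0.68 (without MIN6 nuclear replicate 1) to 1.57 (without replicate 2) when 1 library was left out. Values near the lower end are argued against, since 58 members at a mean FPKM of at least 10 in both tissues still differed by 0.99 (SE 0.09). More cytoplasmic RNA in the MIN6 nuclear libraries cannot be told apart from a difference between the tissues. The test used centred ratios, with medians of −1.35 in MIN6 and −2.63 in liver for these genes. It took the liver median as the MIN6 value without carry-over. The carried share was then 23.2% on the centred scale, which is not a measured share of cytoplasmic RNA. It would leave no centred log2 ratio below −2.11, yet 18.6% of 650 genes lay below it. With a limit set from MIN6 nuclear replicate 1 alone 31.7% of genes lay below, and from replicate 2 alone 3.1%, which keeps this open. The biological difference between liver and a beta-cell line, and the different ways of isolating nuclei, are confounded here and were not tested.

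A gap between the MIN6 nuclear libraries goes with that result: ribosomal protein genes were higher in nuclear replicate 1 than in replicate 2 by a median of 1.03 (log2), 0.84 more than all genes, while the cytoplasmic replicates differed by 0.02. Cytoplasmic RNA of all kinds carried alike into replicate 1 is argued against as the whole reason, since coding genes with like values in nuclear replicate 2 and in the cytoplasmic libraries had a gap smaller by 0.87 (SE 0.06), or by 0.63 (SE 0.04) when matched on nuclear replicate 1. The SEs in this paragraph are over genes and do not measure spread between libraries. Carry-over of some kinds of cytoplasmic RNA stays open, as genes for protein entry into the endoplasmic reticulum had a gap of −0.15 relative to all genes (SE 0.07), but translation factors 0.38 (SE 0.10), proteasome genes 0.34 (SE 0.09) and oxidative phosphorylation genes 0.24 (SE 0.06). GC content, length and expression level left a gap of 0.51 (SE 0.05) after a regression on all of them, so they do not account for all of it. The labels name no biological difference between these replicates and do not say whether they came from separate cultures. No biological explanation was therefore tested, and a loss of this class of mRNA from replicate 2 stays open.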

How the results depend on the processing

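Alternatives for liver, for the tissue comparison and for GC content, and scaling to estimated reads, GC and length corrections and leaving out small RNA, were chosen after the data were seen. With 1 library left out, the lone library of a fraction is assumed to vary like the others. The floor of 3 reads, 3.603 and 2.63 FPKM in liver cytoplasmic libraries, limits liver ratios of low genes. Alternatives for a count table and for a table of means were not run, since the file holds values per library. Where a reason is not evident from the setting (fewer genes tested, a stricter threshold, a shifted median), the cause was not tested.

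Called genes (nuclear, cytoplasmic; 712 and 2775 in MIN6, 303 and 5197 in liver) became 1687 and 1550, 1473 and 1181 with median centring. Rescaled to a sum of 1000000 they became 1088 and 1773, 1513 and 534, and scaled to the estimated reads 1327 and 2108, 2100 and 913. Centring with a GC correction gave 1448 and 1633, 1211 and 1393, and with a length correction 1441 and 1609, 1147 and 1277. A mean FPKM of at least 10 left 109 and 453, 106 and 3588, and an adjusted p under 0.01 left 244 and 1826, 83 and 2496. Pseudocount 0.1, no filter, the trend, the block and leaving out small RNA stayed within 1.5 times. With 1 library left out MIN6 ranged from 0 to 814 and 0 to 2294, and liver from 0 to 370 and 0 to 5535.

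Genes at least 2-fold higher (776 and 2607 in MIN6, 647 and 7043 in liver) became 1613 and 1297, 2819 and 2100 with centring. With 1000000 as the sum, MIN6 nuclear genes were 1676 and liver genes 4040 and 1830, and with the estimated reads 1238, and 3497 and 1578. The GC correction gave 1343 and 1375, 2371 and 2484, and the length correction 1351 and 1415, 2312 and 2454. A mean FPKM of at least 10 gave 156 and 482, 178 and 3757. Pseudocount 0.1 gave 1045 liver nuclear genes. With 1 library left out the ranges were 540 to 986 and 2542 to 2714 in MIN6, 523 to 908 and 6579 to 7482 in liver.

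Lists towards the nucleus and the cytoplasm (4 and 8 in MIN6, 6 and 10 in liver) fell to 0 and 0 in both tissues with an estimated correlation. At a mean FPKM of at least 10 they were 2 and 3 in MIN6, and 2 towards the nucleus in liver. With a pseudocount of 0.1, 3 liver lists lost their call. Fry, which compares no list with others, gave 0 and 16 in liver. The replicate number as a block, with fry, gave 0 and 0 in MIN6 and 1 towards the nucleus in liver. With 1 library left out they were 4 to 4 and 8 to 9 in MIN6, 4 to 6 and 9 to 10 in liver. Nothing in the labels says that equal numbers are pairs, and deviations of equally numbered libraries correlated at 0.0452 in MIN6 and 0.0425 in liver. Under median centring the 20 MIN6 lists and 21 liver lists fixed beforehand kept their side of the threshold. The direction of the test turned in 4 liver lists that did not pass: beta-cell transcription factors and clock genes (to the nucleus), glucose sensing and proliferation (to the cytoplasm).

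Relations at a mean FPKM of at least 10 became 0.33 for length and 0.22 for exon number in MIN6, and −0.41 for level, 0.26 for length, 0.16 for exon number and 0.17 for GC content in liver. Pseudocount 0.1 gave 0.25 for exon number in MIN6, and −0.42, 0.19 and 0.14 for level, length and exon number in liver. With 1 library left out, MIN6 ranged from −0.45 to 0.0153 for level, 0.19 to 0.27 for length, 0.24 to 0.25 for exon number and 0.25 to 0.32 for GC content, and liver from −0.67 to −0.48, 0.19 to 0.21, 0.10 to 0.14 and 0.06 to 0.11.

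Genes differing between tissues (63 and 47) were 7 and 15 with pseudocount 0.1, 29 and 29 at a mean FPKM of at least 10 in both, and 30 and 25 with the block. The GC correction gave 34 more nuclear in MIN6, the authors' scaling 1412, which takes in the different medians of the tissues. With 1 library left out they ranged from 0 to 233 and 0 to 144.

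Of 134 MIN6 genes taken by the naming rule, 15 changed sign with centring, 10 with 1000000 as the sum and 9 with estimated reads, and of 158 liver genes 33, 43 and 40, most of them not named here. Of those named, G6pc in liver became 1.74 with centring, 2.18 with that sum, 2.11 with estimated reads, 1.76 with GC and 1.81 with length correction. Itih3 in liver (main value −0.07) became 2.39, 2.84, 2.77, 2.34 and 2.19 in the same order as G6pc, and −0.82 to 0.68 with 1 library left out. Ddx5 became 0.28 with GC correction in MIN6 and −0.30 to 0.31 with 1 library left out in liver, and Rian in MIN6 −0.29 to 0.73.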

Other observations

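All tests in this part were chosen after the data were seen, including 11 lists of liver functions.

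In liver, 7 of the added lists lay towards the cytoplasm. Of 24 plasma protein genes 23 were cytoplasmic and 0 nuclear, at −2.81 relative to other genes (adjusted p = 1.18e-05). The exception was Itih3, a heavy chain of an extracellular protease inhibitor, at 1322 ± 892 nuclear and 1322 ± 717 cytoplasmic FPKM, a log2 ratio of −0.07 (SE 0.72, adjusted p = 0.939) that was 2.39 after centring. Cytochrome P450 and conjugation enzymes had 28 cytoplasmic and 0 nuclear of 32, at −2.13 (adjusted p = 3.44e-05), with Cyp2e1 at −4.42. The fatty acid hydroxylase Cyp4a14 stood at 922 and 161 nuclear and at 298 and 23.2 cytoplasmic FPKM, and did not pass (adjusted p = 0.246). Apolipoproteins and lipid transfer proteins had 15 of 16 cytoplasmic, at −1.99 (adjusted p = 0.000666), with Apoe at −5.75, and urea cycle and amino acid enzymes 26 of 27, at −1.58 (adjusted p = 0.000706), with the urea cycle enzyme Ass1 at −5.90. Complement and clotting factors had 20 of 24, at −1.51 (adjusted p = 0.00126), with Cfi at −5.58, and fatty acid oxidation 21 of 25, at −1.54 (adjusted p = 0.00253), with Etfa at −5.37. All 6 red blood cell genes were cytoplasmic, at −3.63 (adjusted p = 0.0481). Mature red blood cells have no nucleus, so this direction was given in advance and is no evidence on mRNA held in the nucleus. These 7 lists had adjusted p = 0.745 with an estimated correlation, and 0 nuclear members under the authors' scaling. The hepatocyte list shares 8 genes with the plasma protein list and 4 with the apolipoprotein list. It shares 2 each with the urea and amino acid list and with the P450 and conjugation list. The results of these lists are therefore not independent of the hepatocyte result. After centring, the cytoplasmic and nuclear members were 18 and 1 of plasma proteins, 17 and 2 of the P450 and conjugation list, 8 and 0 of apolipoproteins, 6 and 1 of urea and amino acid enzymes, 7 and 0 of complement, 8 and 1 of fatty acid oxidation, and 4 and 0 of red blood cell genes.

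Fatty acid synthesis (15 cytoplasmic of 19, adjusted p = 0.0530) with Thrsp at −5.94, gluconeogenesis and glycogen (12 of 16, adjusted p = 0.0743), and liver transcription factors (11 of 23, adjusted p = 0.524) did not pass. Cebpa, a hepatocyte transcription factor, was at −4.39, while the xenobiotic receptor gene Nr1i3 was at 0.57 (adjusted p = 0.356, with 74.8% of exon bases shared with other genes). Markers of Kupffer, stellate and sinusoid cells had 6 cytoplasmic and 0 nuclear of 15 (adjusted p = 0.567), with 4 nuclear and 0 cytoplasmic after centring, when the list passed towards the nucleus (adjusted p = 0.0214). Fatty acid synthesis also passed after centring, towards the cytoplasm (7 cytoplasmic and 4 nuclear, adjusted p = 0.0282), while gluconeogenesis (5 and 3) and liver transcription factors (1 and 4, with the direction of the test turned) did not. An estimated correlation was not run after centring. Stab2, a scavenger receptor of sinusoid cells, stood at 26.2 ± 6.12 against 10.3 ± 2.27 FPKM, a log2 ratio of 1.27 (adjusted p = 0.0656). In MIN6 none of the 5 added lists with enough tested genes passed (adjusted p = 0.958 for each). Between tissues, xenobiotic enzymes lay 2.09 further towards the nucleus in MIN6 relative to other genes (7 genes, adjusted p = 5.11e-05), urea and amino acid enzymes 1.53 (8 genes, adjusted p = 0.000704) and fatty acid oxidation 1.07 (14 genes, adjusted p = 0.000704), each with adjusted p = 0.177 with an estimated correlation. These lists are low in MIN6, with a median mean FPKM of 0, 0.09 and 1.40 over all listed members, tested or not. The pseudocount draws ratios of low genes towards 0, so part of these differences may come from the lower level in MIN6.

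Splicing regulators lay above other genes in the nuclear ratio of both tissues at the preset correlation, with adjusted p = 0.320 in MIN6 and adjusted p = 0.534 in liver with an estimated correlation. GC content is argued against as the whole reason, since after a GC correction they still lay 2.05 above other genes in MIN6 (SE 0.21) and 2.83 in liver (SE 0.20), against 1.68 and 2.68 before it, and so is transcript length, with 1.47 and 2.47 after its correction. A hypothesis is that transcripts of such genes may be kept in the nucleus with introns left in. The list was drawn from regulators whose transcripts often keep introns or poison exons. How many members have an annotated retained intron therefore cannot test this hypothesis. Genes with an annotated retained-intron transcript had a higher ratio than matched genes without one by 0.25 in MIN6 (SD 0.09), which goes with the hypothesis but is small beside the 1.50 of the list, and 36 of 39 members have such a transcript, as do 3964 of 5804 coding genes tested. In liver the matched difference of 0.12 (0.17 and 0.06 with each replicate number, SD 0.07) leaves it open, and reads over introns were not analysed here.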
